A study of Homo sapiens with 45 samples.

How the data were processed

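RNA was harvested from trypsinised, pelleted cells with a column kit, and libraries were made from 500 ng of total RNA with the Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name STAR, RSEM 1.3.1 and the hg38 build, without saying which step each served. Whether counting used strand, which annotation was used and which tool gave the splicing events are not given in the sources used here. Antisense and overlapping genes therefore cannot be told apart with certainty.

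The gene tables hold TPM values as deposited by the authors, for 60483 genes in each of 31 libraries. The TPM values of a library sum to between 998827.6 and 999628. The event tables hold a fraction between 0 and 1 per event, as deposited by the authors and per the file headers, the percent intron retention (PIR) of an intron or the percent spliced in (PSI) of an exon or splice site, for 24 libraries. Each lists 645214 events: 400295 introns, 217349 exons, 14544 alternative 3' and 13026 alternative 5' splice sites, with no value for events not measured. These fractions were multiplied to percent for printing. No table holds counts, so depth is unknown, no interval for counting error is given, and only the spread between libraries measures precision. Gene names came from a table that pairs identifiers with symbols, which matched 93.1% of identifiers and 96.4% of the 16602 genes with a mean TPM over 1; positions came from the RefSeq annotation of GRCh38.

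Samples were grouped by their titles. The WT group of MCF10A is named as the labels name it; whether it received the scramble GapmeR that the treatment protocol mentions is not given. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Replicates of a group correlated at 0.97 to 0.995 over TPM and at 0.994 to 0.996 over PIR and PSI, and no 2 replicates of a group held identical values.

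The design was fixed before the data were examined and assumed count tables of genes and transcripts, with a count model. The deposited tables hold TPM and fractions, so limma was used in its place, on log2(TPM + 1) for genes and on the PIR or PSI fraction for events. A fold change is on the log2(TPM + 1) scale, which understates the change of low genes. Genes entered a fit when at least as many libraries as the smallest group holds had a TPM of at least 1. Events entered when every library of the fit had a value and the mean lay between 5 and 95%. Fits held all groups of a series (WT MCF10A, the inducible line at 8 days, the shRNA4 and shRNA5 lines, and the SART3 series for genes; all of MCF10A and the inducible line at both times for events). limma used a variance trend in every fit, and p-values were adjusted by Benjamini-Hochberg over the features of a comparison with a threshold of 0.05. Differences of effects were tested as contrasts of the same fit, and the averages over the 2 hairpins of a series were added after the data were seen, as were the event comparisons in normoxia, of hypoxia within each GapmeR and of differences of effects, which had been planned for genes. The 25 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, and again with an estimated correlation. The estimate rests on the few residual degrees of freedom of these fits. A list call lost with it therefore does not show that the list is unchanged.

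The planned share of reads on retained-intron transcripts needs transcript counts. In its place stands the mean PIR over the introns measured in every library of a cell line, tested by exact two-sided permutation. The named genes follow a rule fixed before the data were examined, with TPM in place of CPM. It takes the 7 largest and 7 smallest log2 changes per comparison among called genes with a symbol, a mean log2 value of at least 3 and no overlap between the groups' values. From each list that passed it takes the 4 members with the smallest p in the list's direction, then SART3 and the lncRNA list everywhere, and the 5 smallest p for events and for differences of effects. Not all of these are printed. LASTR was added from knowledge of the study.

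The tests were run in R 4.3.3 with limma 3.58.1 and the package data.table in version 1.17.8, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. They were run on simulated data with 100 features changed by each of 2 sizes, in 1 draw per comparison. Gene changes of 2-fold and 4-fold were recovered for 0% and 13% in hypoxia (15711 genes) and 71% and 93% at 8 days (16166). Shares were 35% and 73% for shRNA4, 41% and 72% for shRNA5 (18152), 42% and 74% for sh2 and 31% and 71% for sh3 (16849). With 7504 genes called the real cutoff in hypoxia was looser, so 0% and 13% are not the real shares. Event changes of 10 and 30 percentage points were recovered for 6% and 28% in WT hypoxia. Against WT in hypoxia shares were 13% and 25% for GapmeR1 and 5% and 31% for GapmeR2 (10646 events). With dox they were 14% and 44% at 48 hours and 7% and 42% at 8 days (13614). Calls on unchanged genes numbered 0 of 13 calls in the hypoxia comparison, 12 of 176 at 8 days, 4 of 112 for shRNA4, 4 of 117 for shRNA5, 14 of 156 (8.97%) for their average, 10 of 126 for sh2, 8 of 110 for sh3 and 14 of 143 (9.79%) for the SART3 average. Calls on unchanged events numbered 0 of 34 in WT hypoxia, 3 of 41 for GapmeR1 and 5 of 41 (12.2%) for GapmeR2 against WT in hypoxia, 3 of 17 and 5 of 29 (17.2%) for their differences in response, and 3 of 61 and 2 of 51 in the inducible line at 48 hours and 8 days. The share of false calls was therefore above the 5% aimed at in several comparisons. All 5 gene lists shifted by 0.3 on the log2 scale in the 8 day comparison were recovered, with 0 false calls among the 25 lists. Genes were drawn independently here, so false list calls where genes vary together were not tested. In the real 8 day libraries another split of the samples called as many as 15 lists.

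Alternatives planned before the data were examined were no filter on low values or on the event mean, fits of only the compared groups, the replicate number as a block, an estimated list correlation and leaving out each library in turn; the event mean stands in place of the planned filter on transcripts. Alternatives chosen after seeing the data were a pseudocount of 0.1, median-ratio scaling, no variance trend, the arcsine square-root scale, a minimum change of 10 percentage points, other sets of introns and leaving out the MHC region. Comparisons of 3 or more libraries per group were set against other splits of the same libraries, all 10 splits of 3 against 3 and 100 drawn splits of larger sets. For contrasts over several lines or times, labels were shuffled within each line or time. An earlier scheme that shuffled over all libraries was replaced after its results had been seen, because it mixes differences between lines into the residual. It gave the same verdicts: 6 of 100 splits as large for the difference between shRNA4 and shRNA5, 1 and 37 of 100 for genes and lists of their average, and 100 of 100 for the 8 day minus 48 hour events. For shared controls, 100 sets of unchanged groups were simulated. All libraries of the fit, the controls included, were drawn anew, each gene or event independently of the others.

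For the GapmeR and 48 hour libraries gene tables were not analysed here, so their planned gene comparisons were not made.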

Results

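The deposited data came from 45 RNA-seq libraries of human breast cell lines in 17 groups. They were made to ask how a long noncoding RNA that responds to low oxygen affects the efficiency of splicing. MCF10A, a non-tumorigenic mammary epithelial line, was kept in normoxia or in hypoxia at 1% oxygen. These cells were either wild-type (WT) or treated with 1 of 2 GapmeRs, antisense oligonucleotides that direct RNase H to a target RNA, with n = 2 in each of the 6 groups. MDA-MB-231, a triple-negative breast cancer line, carried a tetracycline-inducible shRNA and was grown with or without doxycycline (dox) for 48 hours or 8 days, with n = 3 per group. Lines carrying shRNA4 or shRNA5 were grown with or without dox for 8 days, and a further 3 groups constitutively expressed the SART3 hairpins sh2 or sh3 or a GFP control hairpin, again with n = 3 each. SART3 is a protein that helps assemble the U4/U6.U5 tri-snRNP of the spliceosome. Gene-level TPM tables covered 31 libraries: the WT MCF10A libraries, the inducible line at 8 days, the shRNA4 and shRNA5 lines, and the SART3 series. Splicing event tables covered 24 libraries: all of MCF10A and the inducible line at both times. For the GapmeR libraries and the 48 hour libraries no gene-level table was analysed here. Neither table holds read counts, so the depth of each library is unknown. Between 21214 and 35197 genes per library had a TPM above 0, and between 92938 and 135805 introns per library had a measured percent intron retention.

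The labels do not name the long noncoding RNA. From what is known of the study it is LASTR (ENSG00000242147.1; GRCh38, chromosome 10, 5594984 to 5596118), and its level was examined first, together with SART3 (ENSG00000075856.10; chromosome 12, 108522214 to 108561173). In WT MCF10A cells LASTR rose in hypoxia, 67.2 ± 10.4 against 6.86 ± 0.802 TPM in normoxia (mean ± SD, n = 2 each; log2 change 3.11, limma adjusted p = 3.48e-04). In the inducible MDA-MB-231 line LASTR fell after 8 days of dox, 1.2 ± 0.253 against 5.03 ± 1.16 TPM without dox (n = 3 each; log2 change -1.44, adjusted p = 0.00484). In the shRNA4 line LASTR was at 2.46 ± 1.47 against 5.74 ± 0.465 TPM and in the shRNA5 line at 3.02 ± 1.29 against 5.61 ± 1.98 TPM (n = 3 each). Neither difference passed the test over all genes (adjusted p = 0.678 and 0.697), nor did their average (log2 change -0.88, adjusted p = 0.374). The log2 changes were -1.04 and -0.73 (SE 0.35 each) and stayed negative with any 1 library left out. In the shRNA4 line LASTR was at 1.55 to 4.16 TPM with dox and 5.205 to 6.055 TPM without. The shRNA5 ranges overlapped, 1.53 to 3.83 against 3.37 to 7.09 TPM. A fall of LASTR is therefore not excluded in either line. In the SART3 series LASTR was at 2.50 ± 0.682 with sh2, 1.75 ± 1.43 with sh3 and 2.75 ± 1.27 TPM with shGFP, with no call (adjusted p = 0.987 and 0.680). SART3 fell with both of its hairpins, to 16.1 ± 2.54 TPM with sh2 and 15.8 ± 1.17 TPM with sh3 from 59.3 ± 9.62 TPM with shGFP (n = 3 each; log2 change -1.82 and -1.83, adjusted p = 0.00651 and 0.00623). In WT MCF10A cells SART3 fell in hypoxia, 17.8 ± 0.645 against 30.7 ± 6.70 TPM (log2 change -0.74, adjusted p = 0.0260). That SART3 call was lost without the normoxia library of replicate 2 (log2 change -0.52, adjusted p = 0.125) and without the hypoxia library of replicate 1 or 2 (-0.77 and -0.70, adjusted p = 0.127 and 0.144). The sh2 call on SART3 was lost without the sh2 library of replicate 1 or 3 (-1.78 and -1.74, adjusted p = 0.0684 and 0.0547). With the replicate number as a block SART3 was called with neither hairpin. SART3 was at 35.8 ± 3.45 against 43.8 ± 2.61 TPM in the inducible line at 8 days (adjusted p = 0.0959), 57.7 ± 5.72 against 61.9 ± 3.40 TPM in the shRNA4 line and 65.5 ± 11.4 against 63.3 ± 6.44 TPM in the shRNA5 line, with no call. LASTR could not be followed in the GapmeR or 48 hour libraries, so the knockdown in those groups rests on the labels.

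**Figure D1:**
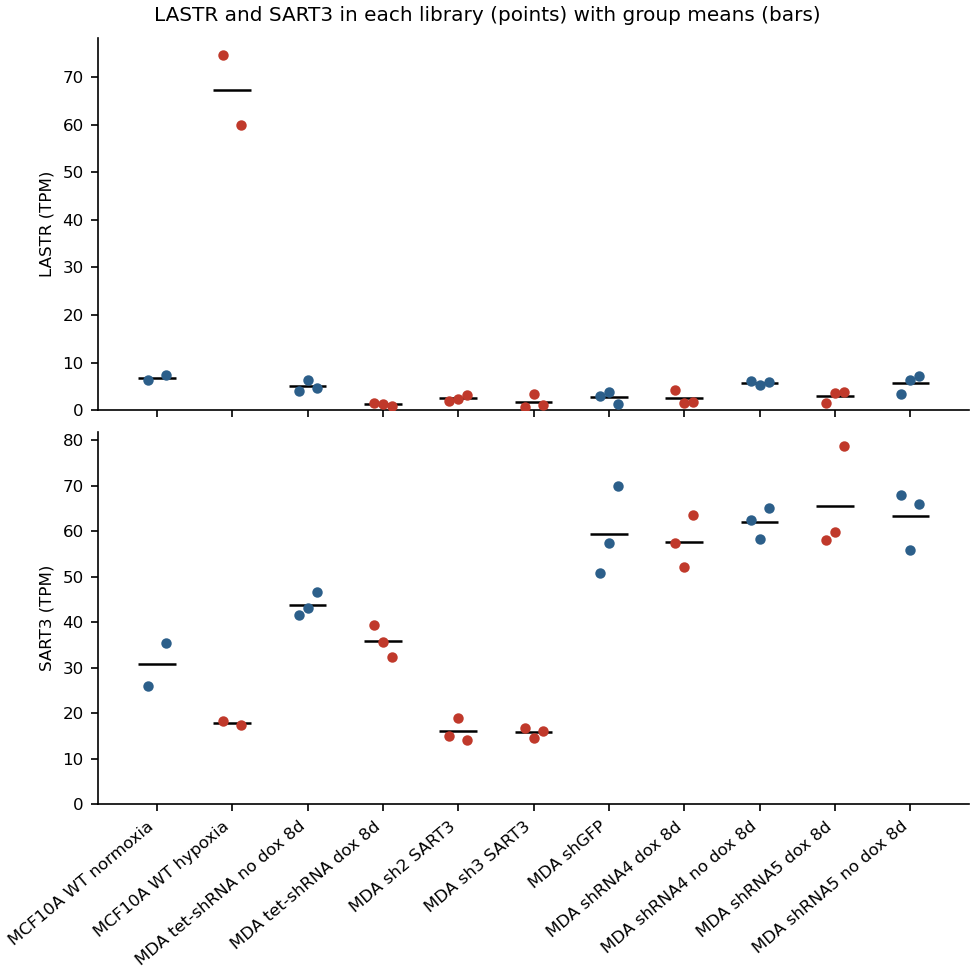
TPM of LASTR (top) and SART3 (bottom) in each library with a gene-level table, by group; points are libraries (red for hypoxia, dox or a SART3 hairpin, blue for the others) and horizontal bars are group means. LASTR was highest in hypoxic WT MCF10A cells, at 59.9 and 74.6 TPM, and SART3 lay between 14.2 and 19 TPM with its own hairpins and at 17.4 and 18.3 TPM in hypoxic WT MCF10A cells.

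The first comparison asked what 1% oxygen does to WT MCF10A cells (n = 2 per group; values are TPM, hypoxia against normoxia, mean ± SD). The largest rises were in genes that HIF transcription factors induce. EGLN3, an oxygen-sensing prolyl hydroxylase (ENSG00000129521.12; chromosome 14, 33924227 to 33951074), reached 456 ± 51 against 1.19 ± 0.302 (log2 change 7.71, adjusted p = 8.87e-05). CA9, a cell-surface carbonic anhydrase (ENSG00000107159.11; chromosome 9, 35673928 to 35681159), reached 390.4 ± 16.7 against 1.95 ± 0.217, and the glycolytic enzyme ENO2 218 ± 20.9 against 1.85 ± 0.446. PPFIA4, IGFBP3, TREM1 and DEPP1 completed the 7 genes with the largest rises, with log2 changes of 6.91, 6.87, 6.44 and 6.41. The 7 largest falls included the fatty acid binding protein FABP5 at 6.70 ± 3.28 against 126 ± 40.9, the complex I assembly factor NDUFAF4 (log2 change -4.05), and CDCA7 and UHRF1, which act in DNA methylation maintenance (log2 change -4.04 and -3.98). The other 3 were HCG25, TCF19 and LSM2 (log2 change -6.24, -4.27 and -3.96), of which TCF19 and LSM2 lie in the major histocompatibility complex (MHC) region of chromosome 6 and HCG25 just beyond it (chromosome 6, 33249536 to 33254890). There, between 29 and 33 Mb, the median log2 change of 121 genes was -1.18, against 0.03 for 31 genes between 34 and 37 Mb. The levels of single genes in and around this region are therefore reported as uncertain. Another processing of the hypoxia tables was not excluded and could touch genes elsewhere too. The gene counts and lists in hypoxia carry that doubt. limma called 7504 of 15711 genes, 3975 higher and 3529 lower. Without the genes of a wider span, 28 to 34 Mb, 7407 of 15543 were called. Without the normoxia library of replicate 1 or 2 the count was 3235 or 3218, without the hypoxia library of replicate 1 or 2 it was 3760 or 4142, and it was 4889 with no filter on low values.

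The lists of HIF targets and of glycolysis genes passed in the higher direction in hypoxia. Of 44 measured HIF targets 43 were called higher and 0 lower, with 43 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.62e-23, and adjusted p = 0.332 with an estimated correlation). Among them NDRG1 stood at 5156 ± 108 against 208 ± 7.89. Of 23 glycolysis genes 18 were called higher and 1 lower, with 20 higher and 1 lower adjusted over the list alone (camera adjusted p = 2.56e-07, and adjusted p = 0.33 with an estimated correlation). Examples were the glucose transporter SLC2A1 at 1224 ± 73.0 against 81.2 ± 6.76, PFKFB4 and HK2 (log2 change 4.37 and 3.55). Respiratory chain lists passed in the other direction. Of 71 nuclear-encoded oxidative phosphorylation subunits 0 were called higher and 41 lower, with 0 higher and 41 lower adjusted over the list alone (camera adjusted p = 1.08e-09, and adjusted p = 0.373 with an estimated correlation). Examples were ATP5MC1 at 56.9 ± 7.66 against 313 ± 50.9 and NDUFS8 at 31.2 ± 0.0311 against 106 ± 5.03. All 13 measured mitochondrially encoded genes were called lower, 13 adjusted over the list alone (camera adjusted p = 2.02e-09, and adjusted p = 0.366 with an estimated correlation). Examples were MT-ND3 at 449 ± 6.02 against 3528 ± 7.60 and MT-CO3 at 572 ± 67.7 against 5124 ± 574. Mitochondrial transcripts made up 1.91 to 2.06% of TPM in the hypoxia libraries and 6.99 to 7.73% in the normoxia libraries.

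Lists of replication, mitosis and homologous recombination genes passed in the lower direction in hypoxia. Of 44 replication and S phase genes 0 were called higher and 43 lower, with 0 higher and 43 lower adjusted over the list alone (camera adjusted p = 1.03e-16, and adjusted p = 0.366 with an estimated correlation). Examples were the ribonucleotide reductase subunit RRM2 at 12 ± 1.01 against 112 ± 1.19 and the replicative helicase subunit MCM3 at 6.69 ± 0.986 against 89.8 ± 21.1. Of 40 mitosis genes 1 was called higher and 34 lower, with 1 higher and 35 lower adjusted over the list alone (camera adjusted p = 7.95e-11, and adjusted p = 0.474 with an estimated correlation). Examples were CDC20 and CCNB1 (log2 change -2.35 and -1.68). Of 24 homologous recombination genes 0 were called higher and 22 lower, with 0 higher and 22 lower adjusted over the list alone (camera adjusted p = 1.07e-07, and adjusted p = 0.373 with an estimated correlation). Examples were EXO1 and ATR (log2 change -2.62 and -2.04). Lists of splicing factors passed in the lower direction as well. Of 30 tri-snRNP proteins and SART3 partners 1 was called higher and 19 lower, with 1 higher and 20 lower adjusted over the list alone (camera adjusted p = 2.6e-06, and adjusted p = 0.332 with an estimated correlation). Examples were PPIH at 18.1 ± 0.780 against 76.4 ± 3.58 and LSM6 at 13.2 ± 1.65 against 59.4 ± 1.10. Of 28 Sm, U1 and U2 snRNP proteins 1 was called higher and 21 lower, with 2 higher and 22 lower adjusted over the list alone (camera adjusted p = 5.01e-07, and adjusted p = 0.332 with an estimated correlation). Examples were SNRPG and SF3B3 (log2 change -1.85 and -1.50). Of 35 SR proteins, hnRNPs and CLK kinases 6 were called higher and 19 lower, with 6 higher and 20 lower adjusted over the list alone (camera adjusted p = 0.00158, and adjusted p = 0.517 with an estimated correlation). Examples were SRSF7 at 37.8 ± 4.65 against 196 ± 2.79 and SRSF10 at 49.2 ± 0.261 against 164 ± 20.7.

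Several lists with other functions passed in the higher direction in hypoxia. Of 29 mesenchymal genes 18 were called higher and 0 lower, with 19 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.26e-06, and adjusted p = 0.33 with an estimated correlation). Examples were the integrin subunit ITGA5 at 726 ± 90.6 against 46.8 ± 0.502 and the collagen cross-linking enzyme LOX at 303 ± 61.8 against 12.4 ± 2.56. Of 21 autophagy and lysosome genes 13 were called higher and 0 lower, with 13 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00153, and adjusted p = 0.517 with an estimated correlation). Examples were CTSB and ULK1 (log2 change 2.34 and 3.52). Of 23 NF-kappaB and cytokine genes 14 were called higher and 3 lower, with 14 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.0351, and adjusted p = 0.517 with an estimated correlation). Examples were CSF2 and IL11 (log2 change 3.8 and 3.87). Of 32 cholesterol and SREBP genes 20 were called higher and 4 lower, with 21 higher and 4 lower adjusted over the list alone (camera adjusted p = 1.62e-04, and adjusted p = 0.517 with an estimated correlation). An example was the sterol sensor INSIG1 at 445 ± 1.67 against 65.3 ± 14.3. Of 23 replication-dependent histone genes 13 were called higher and 0 lower, with 14 higher and 0 lower adjusted over the list alone (camera adjusted p = 8.5e-06, and adjusted p = 0.447 with an estimated correlation). Examples were H2BC5 and H1-2 (log2 change 3.97 and 2.93); these genes have near-identical copies, and how reads were split between them is not given in the sources used here. Of 24 lncRNAs 14 were called higher and 1 lower, with 14 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.89e-04, and adjusted p = 0.366 with an estimated correlation). Examples were MIR210HG at 356 ± 41.7 against 6.42 ± 2.50, LUCAT1 at 91.7 ± 22.9 against 0.978 ± 0.798 and NEAT1, the scaffold of paraspeckles, at 396 ± 27.8 against 152 ± 24.5. The 9 lists that did not pass had adjusted p from 0.0706 to 0.924; they were the NMD-sensitive transcripts, unfolded protein response, interferon, p53, MAPK, epithelial junction, basal keratin, ribosomal protein, and leukocyte, endothelial and fibroblast marker lists. With an estimated correlation none of the 16 list calls held, adjusted p = 0.332 to 0.517. With 2 libraries per group few residual degrees of freedom are left, so this loss does not show that the lists are unchanged.

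**Figure D2:**
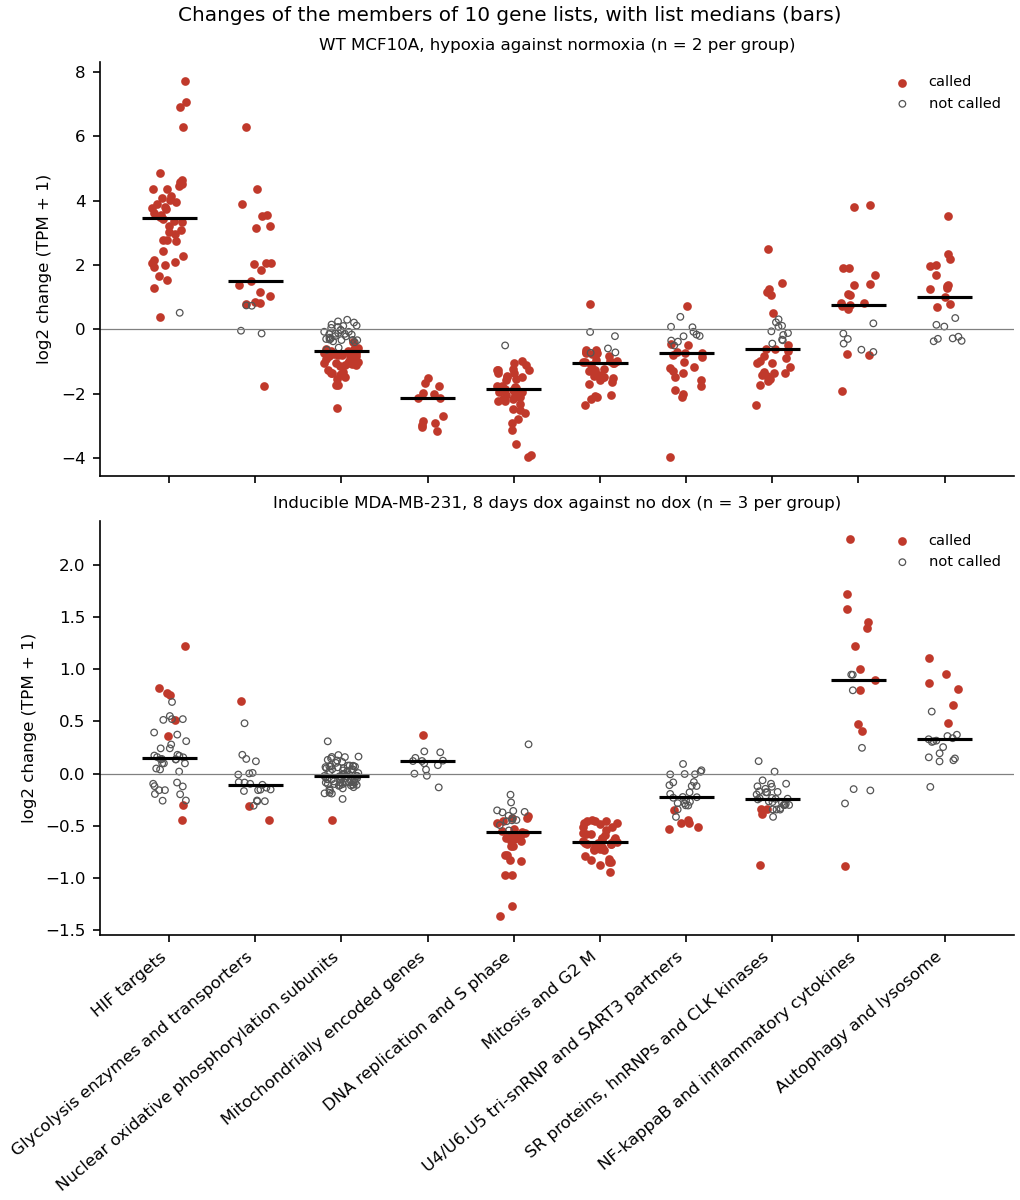
Log2 change (TPM + 1) of every measured member of 10 gene lists, for WT MCF10A hypoxia against normoxia (top) and for 8 days of dox against no dox in the inducible MDA-MB-231 line (bottom); each point is a gene, filled where limma called it, and bars are list medians. In hypoxia 43 of 44 HIF targets were called higher and 43 of 44 S phase genes lower, and with dox all 40 mitosis genes were called lower.

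**Figure D3:**
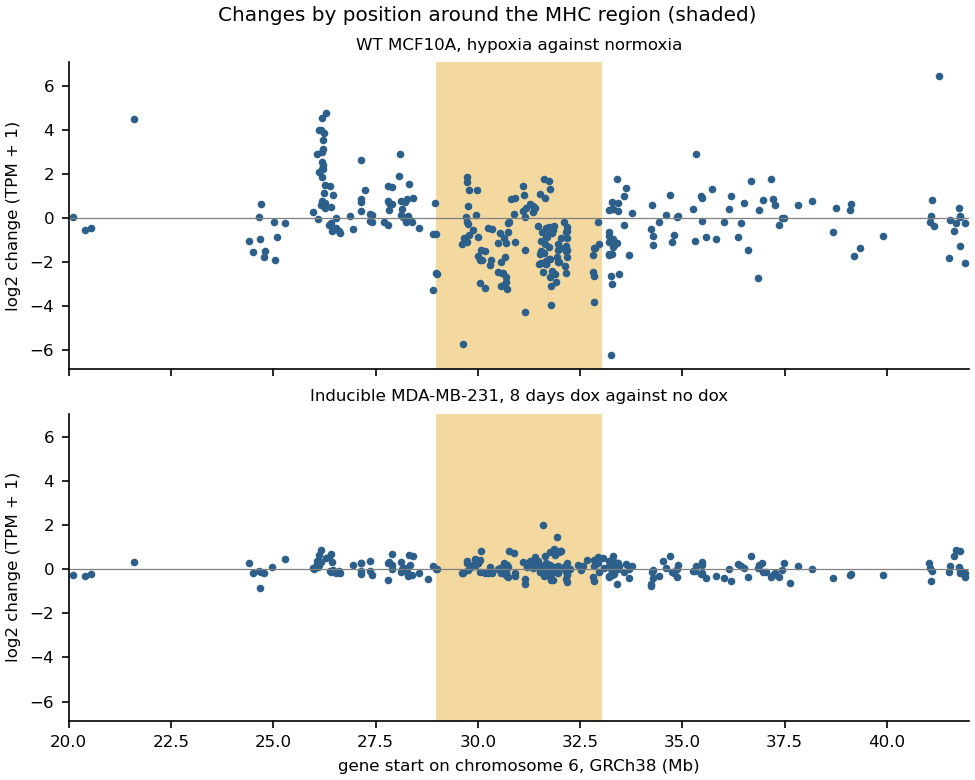
Log2 change (TPM + 1) of each tested gene by its start on chromosome 6 between 20 and 42 Mb, for hypoxia in WT MCF10A cells (top) and for 8 days of dox in the inducible MDA-MB-231 line (bottom); the shaded span is 29 to 33 Mb. In hypoxia the 121 genes of the span had a median of -1.18, against 0.03 for 31 genes between 34 and 37 Mb and 0.69 for 56 genes between 25 and 28 Mb, a stretch that holds a histone gene cluster.

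Splicing in hypoxia was compared in the same WT MCF10A cells, and in the cells given either GapmeR, over 10646 events (n = 2 per group; percent intron retention or percent inclusion, mean ± SD). In WT cells intron event 1 of BOP1, a ribosome biogenesis factor, was retained at 59.7% ± 0.479 in hypoxia and at 0% in both normoxia libraries (adjusted p = 5.47e-04). Exon event 26 of HNRNPAB, an RNA-binding protein, fell from 94.2% ± 2.16 to 46.0% ± 4.45 inclusion. The alternative 5' splice site events 45 of SMARCA2 and 6 of CTSL fell by 24.2 and 20.4 percentage points. Exon event 37 of NBPF26 rose from 34.9% ± 2.25 to 85.2% ± 2.38, in a gene family of near-identical copies between which reads cannot be assigned with certainty. limma called 196 events in 154 genes, 134 higher and 62 lower, among them 38 retained introns higher and 10 lower and 69 exons higher and 38 lower. GapmeR1 cells gave 194 called events in hypoxia against normoxia and GapmeR2 cells 306, and 100 and 119 of these were also called in the same direction in WT cells, where independent lists would share 1.9 and 3.0. With 1 library left out, WT cells gave 32 to 222 called events, GapmeR1 cells 16 to 249 and GapmeR2 cells 131 to 186, the lowest being without the WT normoxia library of replicate 1, the GapmeR1 normoxia library of replicate 2 and the GapmeR2 hypoxia library of replicate 1. Without the WT normoxia library of replicate 2 the balance of retained introns in WT cells reversed, to 14 called higher and 26 lower. In fits of only the compared groups 0 events were called by limma in each of the 3, with 2 libraries per group.

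The GapmeR comparisons asked whether splicing differs when the lncRNA is targeted (n = 2 per group). In hypoxia limma called 5 events in 3 genes with GapmeR2. Exon event 18 of ANKRD54 fell from 100% ± 0 in WT to 63.9% ± 1.62 with GapmeR2 (adjusted p = 1.51e-04). The event was at 100% in every other MCF10A library and passed the filter on the mean only through this group. Groups without spread make its SE small, so a call kept with 1 library left out is weak support. Exon event 12 of SRSF3, an SR splicing factor whose transcript carries a regulatory exon, rose from 30.5% ± 2.08 to 65.7% ± 3.18 (adjusted p = 0.00182); whether event 12 is that exon is not given in the sources used here. Intron event 25 of CLUH rose from 1.72% ± 2.44 to 24.1% ± 1.75 (adjusted p = 0.00948). With GapmeR1 in hypoxia SRSF3 exon 12 was at 42.9% ± 3.18 and ANKRD54 exon 18 at 100% in both libraries, and limma called 0 events, with 1060 of the 10646 at an unadjusted p under 0.05. The events nearest to a call with GapmeR1 were intron event 6 of ROGDI at 29.6% ± 5.24 against 0.495% ± 0.700, exon event 53 of LUC7L3 at 3.15% ± 1.44 against 17.3% ± 0.345 and exon event 16 of MCM8 at 70.0% ± 4.71 against 100% ± 0 (adjusted p = 0.0829 for each). In normoxia limma called 0 events with GapmeR1 and 0 with GapmeR2, with 221 and 714 at an unadjusted p under 0.05. Without the WT normoxia library of replicate 2 these counts were 19 and 16, and without the GapmeR2 normoxia library of replicate 2 GapmeR2 gave 21. The change in the hypoxia response itself was tested as a difference of differences. It passed for 2 events with GapmeR2, ANKRD54 exon 18 (difference -36.1 percentage points, SE 1.82, adjusted p = 0.00175) and SRSF3 exon 12 (difference 33.4 percentage points, SE 2.79, adjusted p = 0.0291), and for 0 events with GapmeR1 by limma, with 561 at an unadjusted p under 0.05. However, the SRSF3 call was lost in 6 of 8 fits with 1 library left out (adjusted p = 0.0130 to 0.203 over the 8; kept without the WT or the GapmeR2 hypoxia library of replicate 1) and on the arcsine square-root scale (0.0771), while the ANKRD54 call was kept in all 8. The CLUH call was lost without the GapmeR2 hypoxia library of replicate 2 (adjusted p = 0.0622). Without the WT hypoxia library of replicate 1 GapmeR1 gave 54 and GapmeR2 69 called events in hypoxia, without the GapmeR1 library of replicate 2 GapmeR1 gave 60, and fits of only the compared groups gave 0 events for GapmeR2. The GapmeR1 difference in response gave 7 events without the WT normoxia library of replicate 2. With no filter on the event mean, GapmeR1 and GapmeR2 gave 128 and 35 events in normoxia, 105 and 259 in hypoxia, and 85 and 119 for the difference in response.

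**Figure D4:**
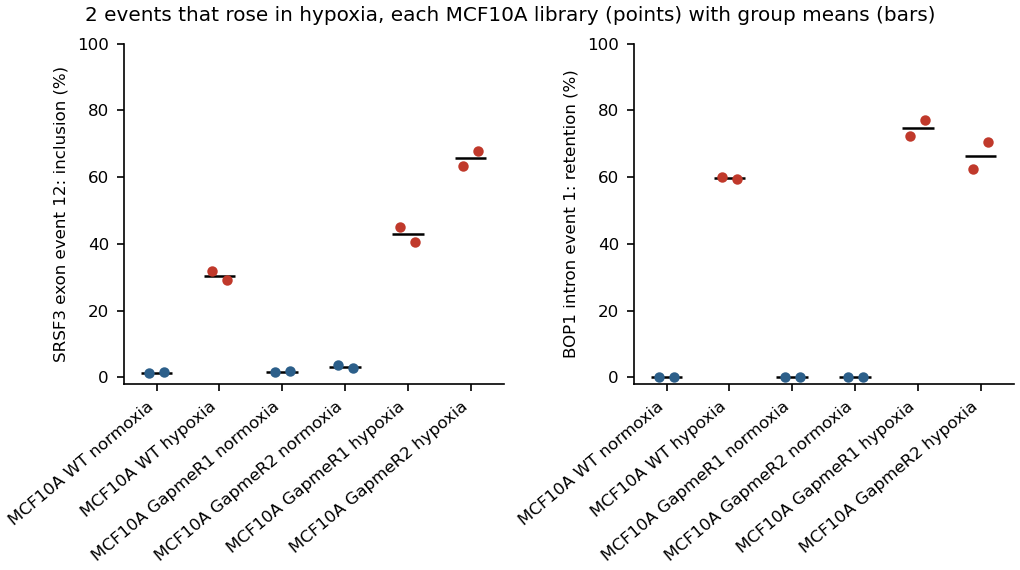
Inclusion of SRSF3 exon 12 and retention of BOP1 intron 1, in percent, in each of the 12 MCF10A libraries; points are libraries (red for hypoxia) and horizontal bars are group means. SRSF3 exon 12 was called higher in hypoxia in each treatment, at 30.5% in WT, 42.9% with GapmeR1 and 65.7% with GapmeR2, and BOP1 intron 1 was at 0% in all 6 normoxia libraries.

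The percent intron retention was also averaged over the introns measured in every library, which are a part of those measured in any 1 library. In MCF10A, over 65674 introns, this mean was higher in hypoxia than in normoxia within WT, GapmeR1 and GapmeR2 cells, 2.89% against 2.59% on average, a difference of 0.300 percentage points (exact permutation p = 0.00926 within treatments, two-sided, the smallest that the 216 arrangements allow). All 6 hypoxia libraries lay above the normoxia libraries of their treatment. The difference was 0.255 in WT, 0.358 with GapmeR1 and 0.287 with GapmeR2 (exact permutation p = 0.33 each, the smallest that 2 against 2 allows). In hypoxia the GapmeR libraries together lay 0.0992 percentage points above WT (exact permutation p = 0.133), and in normoxia 0.0315 above (exact permutation p = 0.533). In the inducible MDA-MB-231 line, over 68370 introns, dox libraries lay 0.139 percentage points above those without dox at 48 hours and 0.0519 at 8 days (exact permutation p = 0.1, the smallest that 3 against 3 allows, and 0.6), and 0.0954 with both times together (exact permutation p = 0.09 within times). Without the dox library of replicate 2 at 48 hours the dox difference was 0.119 with an exact permutation p = 0.04. Over every intron measured in a library, libraries hold different introns, so retention alone is not measured. There the hypoxia difference was 0.839 percentage points (exact permutation p = 0.537), and -2.14 in GapmeR1 alone. That of dox was 2.68 (exact permutation p = 0.015).

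**Figure D5:**
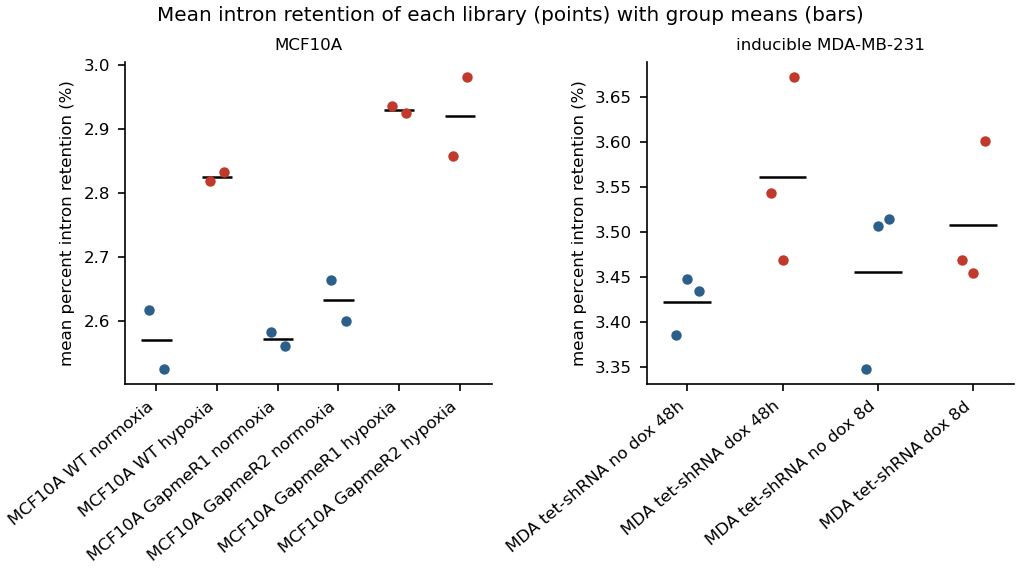
Mean percent intron retention of each of the 24 libraries with event tables, over the introns measured in all libraries of its cell line; points are libraries (red for hypoxia or dox), horizontal bars are group means, and the axes do not start at 0. The 6 hypoxia libraries averaged 2.89% and the 6 normoxia libraries 2.59%.

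In MDA-MB-231 the inducible shRNA was followed for 8 days at the gene level, to ask what changes when the lncRNA is depleted (n = 3 per group; TPM with dox against no dox). The acute-phase proteins SAA1 and SAA2, near-identical copies whose reads cannot be told apart with certainty, stood at 38.7 ± 5.47 against 9.24 ± 0.470 and 49.6 ± 7.45 against 10.8 ± 1.82, and the chemokine CXCL1 at 18.6 ± 8.58 against 2.94 ± 0.881. PRSS2, a trypsinogen with close paralogs, had the largest rise (log2 change 2.42, adjusted p = 0.00555), followed after CXCL1 by the epithelial transcription factor ELF3 (2.11), and TPD52L1 and RARRES2 were also among the 7 largest (1.75 and 1.75). The largest fall was in LASP1, an actin-binding protein (ENSG00000002834.16; chromosome 17, 38870058 to 38921770), at 49.8 ± 6.51 against 199 ± 5.46 (log2 change -1.99, adjusted p = 3.02e-04). SHMT2, the mitochondrial serine hydroxymethyltransferase, was at 56 ± 8.43 against 209 ± 17.2, and the cystine transporter SLC7A11, C12orf75, STK38L, IMPA2 and SLCO4A1 had log2 changes of -1.64, -1.54, -1.50, -1.47 and -1.46. limma called 2126 of 16166 genes, 1130 higher and 996 lower. The count was 462 with no filter on low values, 3589 with median-ratio scaling, and 860, 1319 and 811 without the libraries of replicates 1, 2 and 3 that had no dox, and 626 without the dox library of replicate 2. Libraries with dox had more genes above 0 TPM than those without, 32836 to 35197 against 29325 to 30441, and no group of dox-treated cells without a hairpin was analysed here.

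Lists of proliferation, ribosomal protein and splicing genes passed in the lower direction with dox in the inducible line. All 40 measured mitosis genes were called lower, 40 adjusted over the list alone (camera adjusted p = 6.21e-26, and adjusted p = 0.530 with an estimated correlation). Examples were NUSAP1 at 171 ± 13.8 against 279 ± 9.72 and CDC20 at 151 ± 18.2 against 271 ± 13. Of 44 replication and S phase genes 0 were called higher and 30 lower, with 1 higher and 41 lower adjusted over the list alone (camera adjusted p = 8.79e-19, and adjusted p = 0.530 with an estimated correlation). An example was the sliding clamp PCNA at 83.8 ± 15.6 against 201 ± 19.6. Of 24 homologous recombination genes 0 were called higher and 8 lower, with 0 higher and 16 lower adjusted over the list alone (camera adjusted p = 1.3e-07, and adjusted p = 0.530 with an estimated correlation). Examples were RAD54L and BLM (log2 change -0.69 and -0.75). Of 76 ribosomal protein genes 0 were called higher and 18 lower, with 0 higher and 49 lower adjusted over the list alone (camera adjusted p = 1.81e-17, and adjusted p = 0.530 with an estimated correlation). An example was RPS16 at 740.2 ± 104 against 1343 ± 14.3; many of them have processed pseudogenes. Of 35 SR proteins, hnRNPs and CLK kinases 0 were called higher and 4 lower, with 0 higher and 16 lower adjusted over the list alone (camera adjusted p = 5.68e-08, and adjusted p = 0.530 with an estimated correlation). An example was the SR protein kinase SRPK2 at 17.6 ± 1.77 against 33.1 ± 2.59. Of 28 Sm, U1 and U2 snRNP proteins 0 were called higher and 9 lower, with 0 higher and 12 lower adjusted over the list alone (camera adjusted p = 2.13e-07, and adjusted p = 0.532 with an estimated correlation). Examples were SF3A3 and SNRPB (log2 change -0.64 and -0.51). Of 30 tri-snRNP proteins and SART3 partners 0 were called higher and 6 lower, with 0 higher and 15 lower adjusted over the list alone (camera adjusted p = 2.98e-06, and adjusted p = 0.571 with an estimated correlation). Examples were LSM5 and PPIH (log2 change -0.53 and -0.51). Of 21 NMD-sensitive and snoRNA host transcripts 0 were called higher and 4 lower, with 0 higher and 4 lower adjusted over the list alone (camera adjusted p = 5.26e-04, and adjusted p = 0.593 with an estimated correlation). Examples were SNHG5 and GAS5 (log2 change -0.46 and -0.47).

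Inflammatory, epithelial and lysosomal lists passed in the higher direction with dox in the inducible line, with a part of their members called. Of 19 NF-kappaB and cytokine genes 11 were called higher and 1 lower, with 13 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.67e-05, and adjusted p = 0.530 with an estimated correlation). Examples were RELB and ICAM1 (log2 change 1.00 and 1.45). Of 40 interferon response genes 8 were called higher and 1 lower, with 11 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.67e-04, and adjusted p = 0.530 with an estimated correlation). Examples were OAS1 and IFIT2 (log2 change 1.25 and 0.78). Of 18 epithelial junction genes 9 were called higher and 0 lower, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.66e-06, and adjusted p = 0.530 with an estimated correlation). Examples were CLDN1 and DSP (log2 change 1.01 and 0.73). Of 21 autophagy and lysosome genes 6 were called higher and 0 lower, with 12 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.18e-07, and adjusted p = 0.530 with an estimated correlation). An example was the lysosomal protease CTSD at 2118 ± 279.8 against 979 ± 96.6. Of 33 cholesterol and SREBP genes 4 were called higher and 0 lower, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.72e-06, and adjusted p = 0.593 with an estimated correlation). An example was MSMO1 (log2 change 1.60). Of 44 HIF targets 6 were called higher and 2 lower, with 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0207, and adjusted p = 0.593 with an estimated correlation). Examples were LOX and P4HA2 (log2 change 1.22 and 0.75). Of 6 measured leukocyte, endothelial and fibroblast markers 3 were called higher, 3 adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.530 with an estimated correlation): LUM, COL1A2 and CD14, at 2.54 ± 0.510, 2.76 ± 0.287 and 3.21 ± 1.10 TPM with dox. Of 19 lncRNAs 4 were called higher and 1 lower, with 5 higher and 2 lower adjusted over the list alone, and the list did not pass (camera adjusted p = 0.412). NEAT1 was called higher at 524 ± 17.6 against 230.1 ± 12.8 and UCA1 at 29.4 ± 0.709 against 8.62 ± 2.66. The 10 lists that did not pass had adjusted p from 0.0624 to 0.962. With an estimated correlation none of the 15 list calls held, adjusted p = 0.530 to 0.593. Few residual degrees of freedom are left here too, so this loss does not show that the lists are unchanged.

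Splicing events in the inducible line were tested at 48 hours and at 8 days of dox (n = 3 per group, 13614 events). The events nearest to a call at 48 hours were exon event 17 of ADCY6 at 84.8% ± 4.24 against 100% ± 0, exon event 29 of SPIRE2 at 98.0% ± 3.40 against 82.7% ± 2.38 and intron event 2 of RXRB at 14.6% ± 2.96 against 2.41% ± 1.09 (adjusted p = 0.239 for each). At 8 days they were the alternative 5' splice site event 4 of PIGF at 43.6% ± 3.05 against 22.5% ± 4.97, exon event 27 of GIGYF2 at 14.1% ± 0.407 against 5.16% ± 0.772 and the alternative 3' splice site event 8 of S100A4 at 12.8% ± 1.26 against 20.4% ± 1.61 (adjusted p = 0.202 for each). limma called 0 events at 48 hours, 0 at 8 days and 0 for the difference between the times, with 912, 992 and 750 at an unadjusted p under 0.05. With no filter on the mean, 2 events were called at 48 hours and 11 at 8 days, and 4 were called at 8 days without the no-dox library of replicate 3.

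The shRNA4 and shRNA5 lines asked whether independent hairpins act alike (n = 3 per group; TPM with dox against no dox, 18152 genes). In the shRNA5 line CLNS1A, a chaperone in Sm-ring assembly (ENSG00000074201.7; chromosome 11, 77614530 to 77637794), fell to 82.9 ± 5.01 against 305 ± 15.4 (log2 change -1.87, adjusted p = 1.52e-05). ATP13A2, FASTKD3, CILK1, DCAF13, PAFAH1B2 and the transcription factor ETS1 fell by 1.3, 1.2, 1.12, 1.11, 1.09 and 0.98 on the log2 scale. CYP1B1, C19orf33 and SYNGR2 rose by 0.87, 0.74 and 0.58. In the shRNA4 line the kinase STK24 fell to 40.7 ± 3.81 against 83.4 ± 11 and the Hippo pathway coactivator YAP1 to 58.4 ± 9.04 against 114 ± 6.41 (adjusted p = 0.0381 and 0.0404). limma called 28 genes in the shRNA5 line, 9 higher and 19 lower, and 4 in the shRNA4 line, 1 higher and 3 lower; the other 2 are named here after their values were seen. They were PIP5K1C (log2 change -1.37) and ENSG00000276942.1, a gene with no symbol that was listed at 0 in all 3 libraries without dox and at 4.24 to 8.86 TPM with dox. The difference between the lines passed for 3 genes. The dox effects on CLNS1A and PAFAH1B2 were higher in the shRNA4 line by 1.91 and 1.08 on the log2 scale (adjusted p = 5.25e-04 and 0.0458). The third, ENSG00000266862.1, has no symbol and was listed at 0 in every library of both lines except those of the shRNA5 line with dox, at 4.83 to 7.05 TPM (adjusted p = 0.0458). Averaged over both lines, 13 genes were called, 5 higher and 8 lower, among them CYP1B1 (0.80), FASTKD3 (-0.76), DENND6A (-0.72) and the splicing regulator HNRNPA1 (-0.43). In fits of only the compared groups limma called 0 genes in the shRNA4 line, with 1150 at an unadjusted p under 0.05 in the fit of all groups, and 1 in the shRNA5 line. With 1 library left out the counts were 0 to 3 in the shRNA4 line, 14 to 34 in the shRNA5 line and 1 to 11 for the average, the lowest in the shRNA5 line being without the dox library of replicate 3.

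Among the gene lists, the mitosis and S phase lists passed in the lower direction in the shRNA4 line with dox, and the cholesterol list did so in both lines. These calls held only at the preset correlation. No member of a list was called higher or lower over all genes in the shRNA4 line, and 2 were called lower adjusted over the list alone. The 40 mitosis genes of the shRNA4 line had a median log2 change of -0.26 (camera adjusted p = 7.68e-08, and adjusted p = 0.647 with an estimated correlation) and its 44 S phase genes one of -0.29 (camera adjusted p = 1.62e-06, and adjusted p = 0.647 with an estimated correlation); KIF11, for example, was at 51.6 ± 3.40 against 82.0 ± 10.1. The homologous recombination, Sm, U1 and U2 snRNP, SR protein and cholesterol lists also passed in the lower direction, and the HIF target, glycolysis, oxidative phosphorylation, interferon and ribosomal protein lists in the higher one, none of which held with an estimated correlation (adjusted p = 0.647 to 0.690). In the shRNA5 line the 33 cholesterol genes had a median log2 change of -0.34 (camera adjusted p = 9.34e-05, and adjusted p = 0.876 with an estimated correlation). Its S phase and mitosis genes did not pass and had median log2 changes of 0.11 and 0.11 (camera adjusted p = 0.0721 and 0.0769), the other sign from the shRNA4 line, though the difference between the lines was not tested for lists. The mitochondrially encoded list also passed in the lower direction, and the interferon, basal keratin, histone, ribosomal protein, and leukocyte, endothelial and fibroblast lists in the higher one, none of which held with an estimated correlation (adjusted p = 0.432 to 0.876). Over all genes 0 list members were called higher and 2 lower in the shRNA5 line, and 7 higher and 10 lower adjusted over the list alone. Averaged over both lines 9 lists passed, 6 higher and 3 lower, with adjusted p = 0.456 to 0.810 with an estimated correlation.

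The SART3 hairpins asked what loss of this protein does to gene expression in MDA-MB-231 (n = 3 per group; TPM against shGFP, 16849 genes). With sh3 the extracellular matrix protein TGFBI rose to 237 ± 48.4 against 84.4 ± 21.4 and the chaperone CLU to 191 ± 25.5 against 81.9 ± 9.72, and PLAT and CPA4 rose by 1.07 and 1.03 on the log2 scale. After SART3 itself the largest falls with sh3 were in HLA-DRB1, a gene with close paralogs, the autophagy factor ATG5, and MAPK14, which fell by 1.37, 1.33 and 1.11 on the log2 scale. APIP, SLC25A24 and HMGN2 fell by 1.09, 1.08 and 1.04. With sh2 SERINC2 rose to 64.6 ± 3.45 against 20.8 ± 1.75 and ANKRD1, a target of the Hippo pathway, to 514 ± 37.8 against 278 ± 35.7. limma called 29 genes with sh3, 12 higher and 17 lower, and 5 with sh2, 4 higher and 1 lower; the other 2 with sh2 are named here after their values were seen. The microRNA gene MIR6753 was listed at 0 in all 3 shGFP libraries and at 11.9 to 18.5 TPM with sh2, and ENSG00000280921.1, with no symbol, was at 0 to 0.360 and 6.10 to 10.7 TPM. Averaged over both hairpins 9 genes were called, 7 higher and 2 lower: SART3 (log2 change -1.83) and HMGN2 (-0.64) were lower, and CPA4 (1.11), SERINC2 (0.99), RAB21 (0.61) and TMEM245 (0.59) were among those higher. With 1 library left out the counts were 1 to 9 for sh2, 2 to 15 for sh3 and 1 to 13 for the average. The lowest of the last 2 were without the shGFP library of replicate 1. With the replicate number as a block the counts were 1 for sh2, 0 for sh3 and 0 for the average, and SART3 was not called.

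The gene lists of the SART3 hairpins were set against the same 3 shGFP libraries, so part of the agreement between sh2 and sh3 may come from those libraries. The median log2 change of 76 ribosomal protein genes was -0.12 with sh2 (camera adjusted p = 4.32e-12, and adjusted p = 0.00574 with an estimated correlation) and -0.07 with sh3 (camera adjusted p = 6.21e-05, and adjusted p = 0.0926 with an estimated correlation), with no member called over all genes or adjusted over the list alone. Averaged over the hairpins it was -0.10 (camera adjusted p = 6.96e-10, and adjusted p = 0.0109 with an estimated correlation). The SR protein list was lower as well, -0.10 with sh2 (camera adjusted p = 4.43e-05, and adjusted p = 0.138 with an estimated correlation) and -0.13 with sh3 (camera adjusted p = 2.77e-05, and adjusted p = 0.128 with an estimated correlation). The 44 S phase genes had medians of -0.16 (camera adjusted p = 6.49e-06, and adjusted p = 0.576 with an estimated correlation) and -0.27 (camera adjusted p = 1.57e-12, and adjusted p = 0.194 with an estimated correlation); with sh3 1 of them, FEN1, was called lower, and 10 adjusted over the list alone. The homologous recombination list also passed in the lower direction with both hairpins, and the autophagy and interferon lists in the higher one, none of which held with an estimated correlation (adjusted p = 0.128 to 0.576). With sh3 alone the mitosis and glycolysis lists were lower, and the unfolded protein response, mesenchymal and oxidative phosphorylation lists higher, with adjusted p = 0.128 to 0.711 with an estimated correlation; whether sh2 and sh3 differ in these lists was not tested.

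The last comparison asked which genes or events were shared. Genes called with both sh2 and sh3 numbered 3: SART3, lower, and MIR6753 and a gene with no symbol, higher. The lower one is the target of both hairpins. With 1 library left out they numbered 0 to 3, the lowest without the sh2 library of replicate 1 or 3. Independent lists would share 0.0028 higher and 0.0010 lower genes. Both hairpins were set against the same shGFP libraries. In 100 simulations of unchanged groups, with the shared controls simulated too, no call was shared. Each gene was drawn independently. Where real genes vary together, the simulated spreads below are too narrow to test the observed values. The correlation of the log2 changes across genes was 0.537, against 0.501 ± 0.014 in the simulations (highest 0.546). The covariance was 0.118, against 0.0926 ± 0.00406 (highest 0.105), and 69.4% of genes had the same sign, against 66.7% ± 0.368 (highest 67.5%); the 3 control libraries are too few to split. No gene was called lower in every lncRNA knockdown with a gene-level table, and limma called 0 genes in all of the inducible, shRNA4 and shRNA5 lines, where it called 2126, 4 and 28 genes, and 0 in both the shRNA4 and the shRNA5 line. The log2 changes of the inducible line correlated with those of the shRNA4 line at r = 0.155 and with those of the shRNA5 line at r = 0.046, across genes, which are not independent replicates. Of the 2071 genes called in the inducible line and tested in both fits 71.0% went the same way in the shRNA4 line and 53.4% in the shRNA5 line, against 60.4% and 51% of all 15487 genes. No event was called with both GapmeRs in hypoxia, where limma called 0 and 5 in each, but 29 were without the WT hypoxia library of replicate 1 and 32 with no filter on the event mean. Both were set against the same WT libraries. The correlation of their differences across events was 0.506. It was 0.501 ± 0.015 for simulated unchanged groups with simulated shared controls (highest of 100 simulations 0.540). Events were drawn independently as well, so these simulated spreads carry the same limit. The covariance was 37.3 square percentage points, against 28.9 ± 1.26 (highest 31.9), and 68.0% of events had the same sign, against 66.7% ± 0.440 (highest 68.4%); the 2 control libraries are too few to split.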

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

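The test of the difference between the shRNA4 and shRNA5 lines was planned. The tests of a difference in event response, planned only for genes, and the count over other splits of the samples are tests that were added or chosen only after the data were seen.

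In the shRNA4 and shRNA5 lines 3 genes differed in their response to dox by limma's test of the difference itself, with n = 3 per group. CLNS1A, a chaperone in Sm-ring assembly, stood at 351 ± 11.3 TPM with dox against 343 ± 45 without in the shRNA4 line, and at 82.9 ± 5.01 against 305 ± 15.4 in the shRNA5 line, a log2 difference of 1.91 (SE 0.14, adjusted p = 5.25e-04). PAFAH1B2, a subunit of a platelet-activating factor acetylhydrolase, stood at 98.8 ± 7.65 against 99.2 ± 2.52 and at 41.4 ± 4.12 against 89.1 ± 2.16, a log2 difference of 1.08 (SE 0.14, adjusted p = 0.0458). ENSG00000266862.1, a gene with no symbol, was listed at 0 in 9 of the 12 libraries and at 4.83 to 7.05 TPM in the shRNA5 libraries with dox, a log2(TPM + 1) difference of -2.76 (SE 0.36, adjusted p = 0.0458). Across all genes 14 of 100 splits, the real one included, called at least 3, and the highest other split called 13, so chance cannot be excluded for the count of 3. With any of 8 of the 12 libraries left out, 1 gene was called; these were the shRNA4 library of replicate 3 with dox, those of replicates 1 and 3 without dox, the shRNA5 libraries of replicates 2 and 3 with dox, and all 3 shRNA5 libraries without dox.

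In MCF10A cells 2 exons differed in their response to hypoxia between GapmeR2 and WT cells by the test of the difference, with n = 2 per group. Inclusion of exon event 18 of ANKRD54 stayed at 100% in both conditions in WT cells and in normoxia with GapmeR2. It was 63.9% ± 1.62 in hypoxia with GapmeR2, a difference of -36.1 percentage points (adjusted p = 0.00175). The groups at 100% have no spread, which makes the SE of this event small, also with 1 library left out. Inclusion of exon event 12 of SRSF3 rose by 62.5 percentage points in hypoxia with GapmeR2, to 65.7% ± 3.18 from 3.23% ± 0.453, which was 33.4 percentage points more than in WT cells (adjusted p = 0.0291). The call on SRSF3 was lost in 6 of the 8 fits with 1 library left out (adjusted p = 0.0130 to 0.203 over the 8) and on the arcsine square-root scale (0.0771), while that on ANKRD54 was kept in all 8. In simulated data 5 of the 29 calls of the GapmeR2 test were on unchanged events. For the GapmeR1 difference in response limma called 0 events, with 561 at an unadjusted p under 0.05. No event was called in a fit of only the compared groups, and with 1 library left out 1 to 13 events were called, the most without the GapmeR2 hypoxia library of replicate 1.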

How the results depend on the processing

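Tests that were chosen only after the result was seen are those with a pseudocount of 0.1, median-ratio scaling, no variance trend, the arcsine scale, a minimum change, other intron sets, without the MHC region, every event fit of only the compared groups, and every alternative of an averaged or pooled contrast, of the event comparisons of hypoxia within GapmeRs, of GapmeRs in normoxia and of differences in response. Of the named genes other than SART3 and LASTR, none changed sign in any setting, and 118 of 122 stayed on their side of the threshold with median-ratio scaling, 121 with a pseudocount of 0.1, 96 with no filter and 103 with no variance trend. With 1 library left out, the called named genes that lost their call in at least 1 fit were 0 of 46 in hypoxia, 8 of 42 at 8 days, 2 of 2 for shRNA4, 4 of 10 for shRNA5, 4 of 4 for their average, 1 of 2 for sh2, 9 of 10 for sh3 and 5 of 5 for the SART3 average, and of 10 called named events 2 did (CLUH and the SRSF3 difference in response). Of 25 named genes that had a fit of only the compared groups 17 lost their call there, as did 10 of 19 named events. Where a cause is not stated, the cause was not tested. Depth is unknown for all tables and limits what low genes and rarely covered events can show.

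With no filter on low values, more genes were tested and the counts were 4889 in place of 7504 in hypoxia, 462 in place of 2126 at 8 days, 15 in place of 4 for shRNA4, 21 in place of 3 for the difference between shRNA4 and shRNA5, 26 in place of 13 for their average, and 3 in place of 5 for sh2. SART3 in hypoxia, at -0.74, was then not called. Median-ratio scaling gave 3589 genes at 8 days, with SART3 called at -0.28, and 1 gene for the difference between shRNA4 and shRNA5. A pseudocount of 0.1 gave 1 gene for that difference, 14 for sh2 and 5 shared by sh2 and sh3. Without a variance trend the counts were 17 for shRNA5 in place of 28, 12 for the difference, 21 for the average of shRNA4 and shRNA5, 9 for sh2, and 15 for sh3 in place of 29.

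Fits of only the compared groups have fewer residual degrees of freedom. They gave 0 genes for shRNA4, 1 for shRNA5, 13 for sh2, 16 for sh3 and 1 shared by sh2 and sh3, and limma called 0 events for hypoxia in WT, GapmeR1 and GapmeR2 cells, for GapmeR2 against WT in hypoxia and for the GapmeR2 difference in response. With no filter on the event mean the counts were 55 in place of 196 for hypoxia in WT, 438 and 603 with GapmeR1 and GapmeR2, 128 and 35 for these against WT in normoxia, 105 and 259 in hypoxia, 85 and 119 for the differences in response, 2 at 48 hours of dox, 11 at 8 days and 32 shared by both GapmeRs in hypoxia. The arcsine square-root scale gave 2 events at 48 hours and 1 at 8 days. With an estimated correlation 0 lists were called in hypoxia, at 8 days, for shRNA4, for shRNA5, for their average and for sh3, and 1 list for sh2 and 1 for the averaged SART3 hairpins, where the preset correlation gave 16, 15, 11, 7, 9, 11, 6 and 9.

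Whether the replicate numbers of the labels pair the samples is not given, and the values do not settle it. Same-numbered deviations correlated at -0.033 to 0.243 for genes of the shRNA4 and shRNA5 lines. They did so at -0.100 to 0.111 in the SART3 series and at 0.044 to 0.162 at 8 days. Differently numbered ones correlated at -0.163 to 0.070, -0.080 to 0.076 and -0.154 to 0.056. In MCF10A same-numbered deviations correlated at 0.052 for genes and -0.006 to 0.108 for events. Differently numbered ones mirrored them, at -0.052 and -0.108 to 0.006, as groups of 2 must. With the replicate block, a term for that number, 1 gene was called for the difference between shRNA4 and shRNA5, 1 for sh2, 0 for sh3, 0 for the averaged SART3 hairpins and 0 shared by sh2 and sh3, 14 lists for the average of shRNA4 and shRNA5, and 1 event for the GapmeR2 difference in response. Of the 122 named genes 19 lost their call with it. SART3 then lost its call with sh2, sh3 and both. Its log2 changes of -1.82, -1.83 and -1.83 cannot move with a block in this balanced design. The block changed 2 list calls for shRNA5 (S phase and mitosis, adjusted p = 0.0209 each), 5 for the average of shRNA4 and shRNA5 and 1 for sh2.

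The retained intron differences depended on the introns; which of them count as changed, by sign and by the side of the threshold, was set after their values had been seen. Over every intron measured in a library, GapmeR1 against WT in hypoxia was -0.0767 percentage points and GapmeR1 hypoxia against normoxia -2.14, both reversed, the pooled hypoxia difference was 0.839 (exact permutation p = 0.537), and the pooled dox difference 2.68 (exact permutation p = 0.015); libraries then differ in which introns they hold. Over introns with a mean of 5 to 95% the differences were larger, 2.73 in WT hypoxia, 3.16 pooled over treatments, 0.814 for both GapmeRs in hypoxia and 0.824 for dox over both times.

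Leaving out 1 library at a time, which leaves fewer residual degrees of freedom and sometimes a lone library assumed to vary like the others, gave these ranges. Genes called numbered 3218 to 4142 in hypoxia, 626 (without the dox library of replicate 2) to 2043 at 8 days, 0 to 3 for shRNA4, 14 (without the dox library of replicate 3) to 34 for shRNA5, 1 to 3 for their difference, and 1 (without shRNA4 dox replicate 3 or shRNA5 no-dox replicate 3) to 11 for their average. They numbered 1 (without sh2 replicate 1 or 3) to 9 for sh2, 2 (without shGFP replicate 1) to 15 for sh3, 1 (without shGFP replicate 1) to 13 for the averaged SART3 hairpins, and 0 (without sh2 replicate 1 or 3) to 3 shared by sh2 and sh3. Lists numbered 6 to 11 for shRNA4, 5 to 15 for shRNA5 and 3 to 14 for their average, the lowest for shRNA4 and for the average without shRNA4 no-dox replicate 1 and both highest without shRNA5 no-dox replicate 1. Events numbered 32 (without WT normoxia replicate 1) to 222 for hypoxia in WT, 16 (without GapmeR1 normoxia replicate 2) to 249 in GapmeR1 and 131 to 186 in GapmeR2 cells. Against WT they numbered 0 to 19 (without WT normoxia replicate 2) for GapmeR1 and 0 to 21 (without GapmeR2 normoxia replicate 2) for GapmeR2 in normoxia, and 0 to 60 (without GapmeR1 hypoxia replicate 2) and 4 to 69 (without WT hypoxia replicate 1) in hypoxia. The differences in response gave 0 to 7 and 1 to 13, dox at 8 days 0 to 4 (without no-dox replicate 3), and events shared by both GapmeRs 0 to 29 (without WT hypoxia replicate 1).

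Retained introns at 8 days ranged from -0.00233 (reversed, without no-dox replicate 1) to 0.0810 percentage points, for both GapmeRs in normoxia from -0.0149 (reversed, without WT normoxia replicate 2) to 0.0778, and for dox over both times from 0.0676 to 0.119 (exact permutation p = 0.04, without dox replicate 2 at 48 hours). SART3 ranged from -0.96 to -0.52 in hypoxia and from -1.94 to -1.70 with sh2. It was not called in any of these fits for shRNA5, at -0.10 (without dox replicate 3; -0.04 without no-dox replicate 2) to 0.12, or for the average of shRNA4 and shRNA5, at -0.10 to 0.01 (0.0072 without shRNA5 dox replicate 1 and 0.0031 without shRNA4 dox replicate 2). LASTR with sh2 ranged from -0.35 to 0.17, above 0 without sh2 replicate 1 (0.08), shGFP replicate 1 (0.01) or shGFP replicate 2 (0.17), never called.

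Planned but not run, since the tables hold no counts: DESeq2, the RLE normalization, voom with diffSplice, and the median over genes with at least a minimum of counts. TPM and the separate gene tables, planned as alternatives, became the values of every gene comparison. The gene-level alternatives of the GapmeR and 48 hour libraries were not run because no gene-level table of these libraries was analysed here.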

Other observations

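Tests that were chosen only after the result was seen are those on the MHC region, on a single dox library, on loss of the lncRNA and all counts over other splits of the samples.

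Among other events, retention of intron event 6 of SRSF3, an SR splicing factor, was lower in hypoxia in each treatment. It was 11.7% ± 1.87 against 47.5% ± 5.0 in WT, 9.25% ± 3.05 against 42.1% ± 3.0 with GapmeR1 and 8.13% ± 2.82 against 48.6% ± 3.44 with GapmeR2 (n = 2 each; limma adjusted p = 0.00520, 0.00610 and 0.00196). Of lists that did not pass in hypoxia, 13 of 25 p53 targets were called higher and 3 lower (camera adjusted p = 0.116), 14 of 31 unfolded protein response genes higher and 5 lower (0.123), 7 of 42 interferon genes higher and 15 lower (0.0706), and 10 of 21 epithelial junction genes higher and 2 lower (0.0993). Across 13280 genes, which are not independent replicates, the log2 changes of hypoxia in MCF10A and of 8 days of dox in the inducible MDA-MB-231 line correlated at r = 0.271.

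In hypoxia the 121 genes of the MHC region had a median log2 change of -1.18, and 55.4% of them lay below -1, while the flanks had medians of 0.69 (25 to 28 Mb) and 0.03 (34 to 37 Mb). Less RNA of these genes in hypoxic cells is argued against by the splicing events of the same libraries. In the region's 56 lowered genes, with a median log2 change of -1.90, the log2 ratio of measured events was -0.0571, while 1000 matched sets of genes elsewhere ranged from -0.473 to -0.148. Another reference or read assignment behind the hypoxia tables is a candidate explanation that stays open, because the other regions with alternate copies gave mixed values. On 13 and 11 genes, 19q13.4 lay -0.25 and 17q21.31 lay -0.51 from their flanks. Such a difference would coincide with hypoxia for every gene, and its reach beyond the region was not tested.

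The inducible line gave 2126 called genes at 8 days, against 4 and 28 in the shRNA4 and shRNA5 lines. The lines differed in precision. In simulated data 71% of 2-fold changes were recovered in the inducible line, against 35% and 41% in the shRNA4 and shRNA5 lines. Replicates correlated at 0.9901 to 0.9948 over TPM in the inducible line and at 0.9723 to 0.9774 in the shRNA4 and shRNA5 lines. The gap in counts therefore does not measure how the effects differ, and how much of it comes from precision was not tested. Deeper dox libraries would add calls among low genes, but 27.7% of the called genes had a mean under 10 TPM, against 44.2% of those tested. A single dox library is argued against, since refits without the dox library of replicate 1, 2 or 3 called 2043, 626 and 2039 genes; in replicate 3 a single rRNA-like gene took 2.90% of TPM. Loss of the lncRNA cannot be told apart from other effects of dox in this line, because of the 2071 called genes tested in both fits 71.0% changed the same way in the shRNA4 line, against 60.4% of all genes, but 53.4% in the shRNA5 line, against 51% of all genes, and no cells with dox and no hairpin were analysed here.

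Mean intron retention in MCF10A was higher in hypoxia by 0.300 percentage points. A difference in the number of introns measured is argued against by a hypoxia coefficient of 0.291 (SE 0.0286) when that number was a term of the model. The 1% of introns that changed most are argued against as the whole source, as 0.757 of the difference was kept without them. Over all introns, which include those at 0 in every library, the median change was 0 and 46.7% were higher. Among the 49062 introns above 0 in any library 62.55% were higher, with a median change of 0.0942 and a mean of 0.401. Introns of genes not called in hypoxia had a mean change of 0.270 percentage points, 0.901 of the mean change over all introns. Those of genes called higher and lower had means of 0.290 and 0.370. This argues against called expression changes as the whole source, though genes not called are not shown to be unchanged. A biological rise in retention is a hypothesis that no test here decides, from 1 experiment and with depth unknown. The mean over every measured intron (exact permutation p = 0.537) cannot decide it, because libraries then hold different introns.

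Other splits of the same libraries were refitted, with the real split counted among them. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 2126 genes at 8 days and the highest other 1, with 15 and 15 for lists. For shRNA4 these were 0 and 5 genes and 12 and 10 lists, and for shRNA5 1 and 5 genes and 6 and 16 lists. They were 13 and 10 genes and 8 and 10 lists for sh2, and 16 and 5 genes and 11 and 13 lists for sh3, and 0 and 0 events at 48 hours and at 8 days. Over 100 drawn splits the share was under 0.05 for the genes of the averaged shRNA4 and shRNA5 lines (13, highest other 13, 2 splits as large; 1 gene without shRNA4 dox replicate 3 or shRNA5 no-dox replicate 3) and of the averaged SART3 hairpins (9, highest other 24, 4 as large; 1 gene without shGFP replicate 1). The drawn splits were not checked for repeats of the real one or its mirror image. Both averages were added after the data were seen, and adjusted over the 6 counts drawn this way both shares are 0.12. Chance therefore cannot be excluded for either count. It cannot be excluded for the lists of these averages (9 and 18, 36 as large; 9 and 14, 29 as large) or for the 8 day minus 48 hour events (0 and 4, 100 as large). The split that called 24 genes may point to a structure of the SART3 samples, for which no test was made.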
